A study of Mus musculus with 8 samples.

How the data were processed

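RNA of sorted CD4 and CD8 T cells from a mixed lymphocyte reaction, with or without costimulation blockade, was hybridized to 8 Affymetrix Mouse430_2 arrays. The groups and replicate numbers came from the sample titles, with 2 arrays in each of 4 groups. One protocol label calls the staining antibodies for CD4 and CD8 anti-human although the cells were murine; it was not used.

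The deposited table held 45101 probe sets, 64 of them array controls, and the 45037 others were tested. Its values lay between -5.03 and 4.93, and each probe set had a median of 0 over the 8 arrays (largest deviation 5e-07), so the authors had expressed each value relative to the median of its own row. The values were taken as log2 values normalized between arrays by the authors; the log base, the summary method and the normalization are not given in the sources used here, and log2 was read from the header of the authors' deposited list, which has the layout of a program whose normalized values are log2. If the base were another one, every log2 change would be scaled by one factor, and no p-value would change. Centring by row leaves differences between arrays as they were and removes the signal level, so no statement could be made on how strongly a gene was expressed, and no depth or detection call was used.

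A second deposited file listed 409 probe sets with the same log2 values, each equal to that in the first file, and their gene annotation. Per the file headers, it was made with an unpaired test at a corrected p of at most 0.05 on averaged conditions, with the pair of conditions left blank, and it held no p-values or folds. All 409 differed by at least 2-fold between the means of the 4 blockade and the 4 untreated arrays (smallest log2 difference 1.00). Of the 568 probe sets on the array with such a difference, 500 had an adjusted p of at most 0.05 in an equal-variance test of 4 against 4 arrays adjusted over those 568 alone, and 408 of these were in the list; 92 were not, for a reason not given in the sources used here.

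Gene names were taken from that list alone. Of its 409 probe sets, 375 had 1 gene, 22 had several and 12 had none, and 57 ended in _s_at or _x_at, which can bind transcripts of related genes. For 369 the Entrez identifier was found in a RefSeq gene table of GRCm38.p6, used for names only, and 33 symbols were updated; the others kept the name in the file. The 289 genes named this way included 62 with more than 1 listed probe set. For values of named genes the listed probe sets of a gene were averaged before the fit, which left 44951 features. No gene's listed probe sets differed in sign; those of Ccl6, Il2ra, Rtp4 and Socs2 differed by over 1 log2 unit in CD4 cells, and those of 7 genes in CD8 cells, among them Ccl6, Il2ra, Rrm2 and Tnfrsf9. No probe set with several genes or none was named; 4 of those with several were hemoglobin probe sets, reported only as such.

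The values were fitted in limma 3.58.1 (R 4.3.3) with a mean per group over all 8 arrays and eBayes, two-sided, with Benjamini-Hochberg adjustment over all features of a contrast and a threshold of 0.05. The fit had 4 residual and 4.46 prior degrees of freedom. The contrasts were blockade minus untreated in CD4 and in CD8, their difference, their mean, and CD8 minus CD4 at each treatment. Before the data were examined, the plan was to fit 1 probe set per gene, chosen by its mean signal, with an intensity trend and a filter on dim probe sets as an alternative. With centred values and names for the listed probe sets only, none of these could be done, and all probe sets were tested without a trend. The fit was also run on simulated data, for the contrast in CD4 over 45037 features. The noise was independent and normal, with variances drawn from the fit's own estimated prior. The fit recovered 81% of 100 features changed by 1 log2 unit and 100% of 100 changed by 2, with 10 false calls. These data followed the assumptions of the fit, so they do not show how many false calls the real data hold.

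Before the data were examined, 37 gene lists were fixed with 824 entries, of which 134 could be named; 8 lists had no named member and 12 had at least 3 and were tested. camera with a preset correlation of 0.01 compared the members with the other named genes only, adjusted over the 12 lists of a contrast. Because all named genes come from a list selected on these arrays, a list test shows only how its members lay among genes already selected for a change, most of which fell. The anergy-associated and the naive and memory lists had negative medians and means in both subsets but an upward direction by camera, and for the difference between subsets mitosis, DNA replication and neutrophil genes had positive medians and means but a downward direction, none of them past the threshold. The genes named in the text followed a rule fixed before the data were examined: for each blockade effect the 10 largest rises and falls past the threshold with both blockade arrays on one side of both untreated arrays, up to 4 members of each list with the smallest p, and 14 genes in any case; for the other contrasts the 5 largest each way. Predicted genes and clones were counted but not named, and the values of 1 gene are not reported here.

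The 2 arrays of a group differed from each other in every group (SD of the difference between the 2 arrays 0.20 to 0.24). The alternatives were the replicate number as a block, array weights, quantile normalization, centring of each array on its median, fits of only the 4 arrays compared, the methods' t-test, stricter thresholds, averaging of listed probe sets, and leaving out each array in turn, when the lone array of a group is assumed to vary like the other groups. Leaving out both CD8 blockade replicate 1 and CD4 untreated replicate 2, which had the highest and lowest spike-in medians, the overlap of separate fits of each subset, and Fisher's exact test of the direction of list members were chosen after seeing the data. The 2 arrays with the highest 18S medians, CD4 and CD8 blockade replicate 2, were left out only 1 at a time. Count-based tools were not used.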

Results

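Gene expression was measured on 8 Affymetrix mouse genome arrays in T cells recovered from a mixed lymphocyte reaction, a culture in which lymphocytes of one mouse strain respond to those of another. C57BL/6 splenocytes carrying the dye CFSE were the responders, at 200000 per well. FVB/N splenocytes irradiated with 30 Gy were the stimulators, at 800000 per well. Cultures ran for 5 days without antibody or with a costimulation blockade of CTLA4-Ig, anti-LFA-1 and anti-CD40L, 50 µg of each. CFSE-labelled CD4 or CD8 cells were then sorted. The 4 groups were untreated and blockade-treated CD4 cells and untreated and blockade-treated CD8 cells, with 2 arrays in each. The labels name 4 mice per group but do not say that the 2 arrays of a group came from separate cultures. The p-values therefore measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision.

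The deposited values were differences from each probe set's median over the 8 arrays. They are read here as log2, although the log base is not given in the sources used here. Each change below is blockade minus untreated (log2, ± SE, n = 2 and 2 arrays) unless another contrast is named, and adjusted p-values are limma's with Benjamini-Hochberg adjustment. Gene names were paired only with the 409 probe sets of the authors' deposited list, which was selected on these same arrays, and 289 genes could be named. The direction of a named gene, and every count of gene list members below, is therefore not independent evidence. Of 14 genes to be followed in any case, only Gzmb, Il2ra and Mki67 could be named. The others, among them Cd4, Cd8a, Ifng, Il2, Foxp3 and Ctla4, could not be named, and any probe sets of theirs were tested only without a name. The sorted subsets could therefore not be checked by name against their own marker genes. On the array of CD8 blockade replicate 1, the hybridization spike-in probe sets had a median of 0.92 and the poly-A spike-ins one of 0.84, relative to their 8-array medians. On that of CD4 untreated replicate 2, these medians were -0.23 and -0.48.

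The first comparison asked what costimulation blockade did to CD4 cells responding to alloantigen. The change was -5.77 ± 0.17 for Socs2 (a suppressor of cytokine signalling, itself induced by cytokines; adjusted p = 1.2e-06) and -5.41 ± 0.34 for Gzmb (granzyme B, a cytotoxic protease; adjusted p = 6.7e-05). It was -5.16 ± 0.11 for Iigp1 (an interferon-inducible GTPase), -4.86 ± 0.16 for Tnfrsf9 (the costimulatory receptor CD137) and -4.21 ± 0.32 for Il2ra (the alpha chain of the interleukin-2 receptor). Dnah7b (an axonemal dynein heavy chain) changed by -4.82 ± 0.21, Itih5 by -4.54 ± 0.15, Cpa3 (mast cell carboxypeptidase) by -4.17 ± 0.20, Ifitm3 by -4.13 ± 0.27 and Ifit3 by -4.10 ± 0.10. The largest rises among named genes were smaller. Crisp3 (a cysteine-rich secretory protein) rose by 3.64 ± 0.18, Apoe (apolipoprotein E) by 2.43 ± 0.13, Cr2 (complement receptor) by 2.34 ± 0.14, Egr2 (a transcription factor induced by antigen receptor signalling) by 2.28 ± 0.17 and Fcer2a (the low-affinity IgE receptor) by 2.20 ± 0.17. S1pr3, Rasgrp3, Fabp4, Il4i1 and Pik3ap1 rose by 1.93 to 2.18. Among probe sets with no name here, 1417185_at and 1458589_at fell most (-5.14 ± 0.15 and -4.78 ± 0.14), and 1460118_at and 1458341_x_at rose most (2.31 ± 0.13 and 1.98 ± 0.11).

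Genes of cell division fell together in CD4 cells. Of 22 named members of the mitosis and cell cycle list, 20 fell and 2 did not pass (22 adjusted over the list alone). Mki67 (a proliferation marker) changed by -2.22 ± 0.17, Top2a (topoisomerase) by -2.35 ± 0.19, Cdk1 by -2.04 ± 0.17 and Bub1 (a spindle checkpoint kinase) by -2.49 ± 0.23. The list lay below the other named genes by camera (adjusted p = 0.039; adjusted p = 0.71 with an estimated correlation). In the DNA replication list 4 of 5 members fell (5 adjusted over the list alone). Rrm2 (ribonucleotide reductase) changed by -2.15, Uhrf1 by -2.21, Cdc6 by -2.12 and Tk1 (thymidine kinase) by -1.52. This list did not stand apart from the other named genes (camera adjusted p = 0.45).

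Interferon-inducible genes also fell in CD4 cells. All 17 named members of the type I interferon list fell (17 adjusted over the list alone; camera adjusted p = 0.0076; adjusted p = 0.33 with an estimated correlation). Beside Ifit3, Ifit1 changed by -3.71 ± 0.12, Rtp4 by -3.06 ± 0.12 and Zbp1 by -2.77 ± 0.10. Of 17 named members of the interferon-gamma list, 16 fell and 1 rose (17 adjusted over the list alone; camera adjusted p = 0.0078; adjusted p = 0.66 with an estimated correlation). The guanylate-binding proteins Gbp6 and Gbp2 changed by -4.02 ± 0.10 and -3.29 ± 0.09, and Irgm2 by -3.27 ± 0.10. The member that rose was Ciita (the MHC class II transactivator), at 1.34 ± 0.12, named after its value was seen. Cd274 (the inhibitory ligand PD-L1) changed by -2.91 ± 0.11.

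All 5 named effector cytokines and chemokines fell in CD4 cells (5 adjusted over the list alone; camera adjusted p = 0.24). Penk (proenkephalin) changed by -4.09 ± 0.22, Csf2 (GM-CSF) by -2.40 ± 0.13, Ccl3 by -2.26 ± 0.16, Ccl9 by -2.01 ± 0.42 and Cxcl10 by -1.67 ± 0.19. All 4 named activation receptors fell (4 adjusted over the list alone; camera adjusted p = 0.30), with Tfrc (transferrin receptor) at -1.31 ± 0.22 and Cd69 at -1.01 ± 0.16 beside Tnfrsf9 and Il2ra. Of 3 named anergy-associated genes, Egr2 rose, the nuclear receptor gene Nr4a3 fell (-2.17 ± 0.20) and Nr4a2 lay at -1.08 ± 0.25 without passing (3 adjusted over the list alone; camera adjusted p = 0.70). Of 3 naive and memory T cell genes, Il7r (the interleukin-7 receptor) rose by 1.27 ± 0.09, while Bcl2 (an inhibitor of apoptosis) changed by -1.62 ± 0.10 and Treml2 by -0.89 ± 0.11 (3 adjusted over the list alone; camera adjusted p = 0.81). All 3 named integrated stress response genes fell (3 adjusted over the list alone; camera adjusted p = 0.38). The asparagine synthetase gene Asns fell by 2.00 ± 0.22, Psat1 (serine synthesis) changed by -1.52 ± 0.17 and Wars by -1.44 ± 0.10.

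Markers of other cell types moved with the treatment in the sorted CD4 samples. All 13 named B cell markers rose (13 adjusted over the list alone; camera adjusted p = 2.7e-08; adjusted p = 0.33 with an estimated correlation). Beside Cr2, Fcmr (the IgM Fc receptor) rose by 1.89 ± 0.12, Cd72 by 1.82 ± 0.11 and Cd22 by 1.56 ± 0.10. Of 8 named genes of MHC class II antigen presentation, 7 rose and Cd86 fell (-1.17 ± 0.20; 8 adjusted over the list alone; camera adjusted p = 4.4e-04; adjusted p = 0.36 with an estimated correlation). H2-Ab1, H2-Eb1, H2-Aa and Cd74 rose by 1.43 to 1.70. Of 9 named neutrophil markers, 7 fell and 2 did not pass (9 adjusted over the list alone; camera adjusted p = 0.21). S100a8 changed by -3.91 ± 0.34, Ctsg (cathepsin G) by -2.91 ± 0.12, Mpo (myeloperoxidase) by -2.33 ± 0.13 and Prtn3 by -1.70 ± 0.19. The 4 hemoglobin probe sets of the authors' list, each assigned there to 2 genes and so counted under no gene name, rose by 0.94 to 1.61; without CD4 untreated replicate 2 the calls of 2 of them were lost (adjusted p 0.053 and 0.16), and 1 of these 2 was also lost without either CD4 blockade array (0.11 and 0.15). The 5' minus 3' difference of the Gapdh control probe sets, which were centred like all others, was 0.007 and -0.046 on the blockade arrays and 0.099 and 0.035 on the untreated arrays (beta-actin -0.020 and -0.004, and -0.033 and 0.017).

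In all, 1650 of 45037 probe sets passed a limma adjusted p of 0.05 in CD4 cells, 675 higher and 975 lower under blockade (176 and 476 with a change of at least 2-fold), and 1256 of them were outside the authors' list. Leaving out 1 array gave 797 (without CD4 blockade replicate 1), 768 (without CD4 blockade replicate 2), 1075 (without CD4 untreated replicate 1) or 769 (without CD4 untreated replicate 2). At adjusted p of 0.074 to 0.25 with the direction kept, the calls of Ccl9 and Fabp4 were lost without any 1 of the 4 CD4 arrays, those of Cdc6, Tk1 (-1.01 without CD4 untreated replicate 2), Tfrc and Cd69 without either blockade array or untreated replicate 2, and that of Cd86 without blockade replicate 2 or untreated replicate 2. Ccl9 was also lost without either CD8 blockade array (0.062) or with quantile normalization (0.064), and Fabp4 and Tk1 without either CD8 untreated array (0.051 and 0.066), and Ccl9, Cdc6, Tfrc and Cd86 without both CD4 untreated replicate 2 and CD8 blockade replicate 1, the arrays with unusual spike-ins (0.17 to 0.27), while Nr4a2 passed without CD4 untreated replicate 1 (0.026), without either CD8 untreated array (0.042) or with quantile normalization (0.033).

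**Figure D1:**
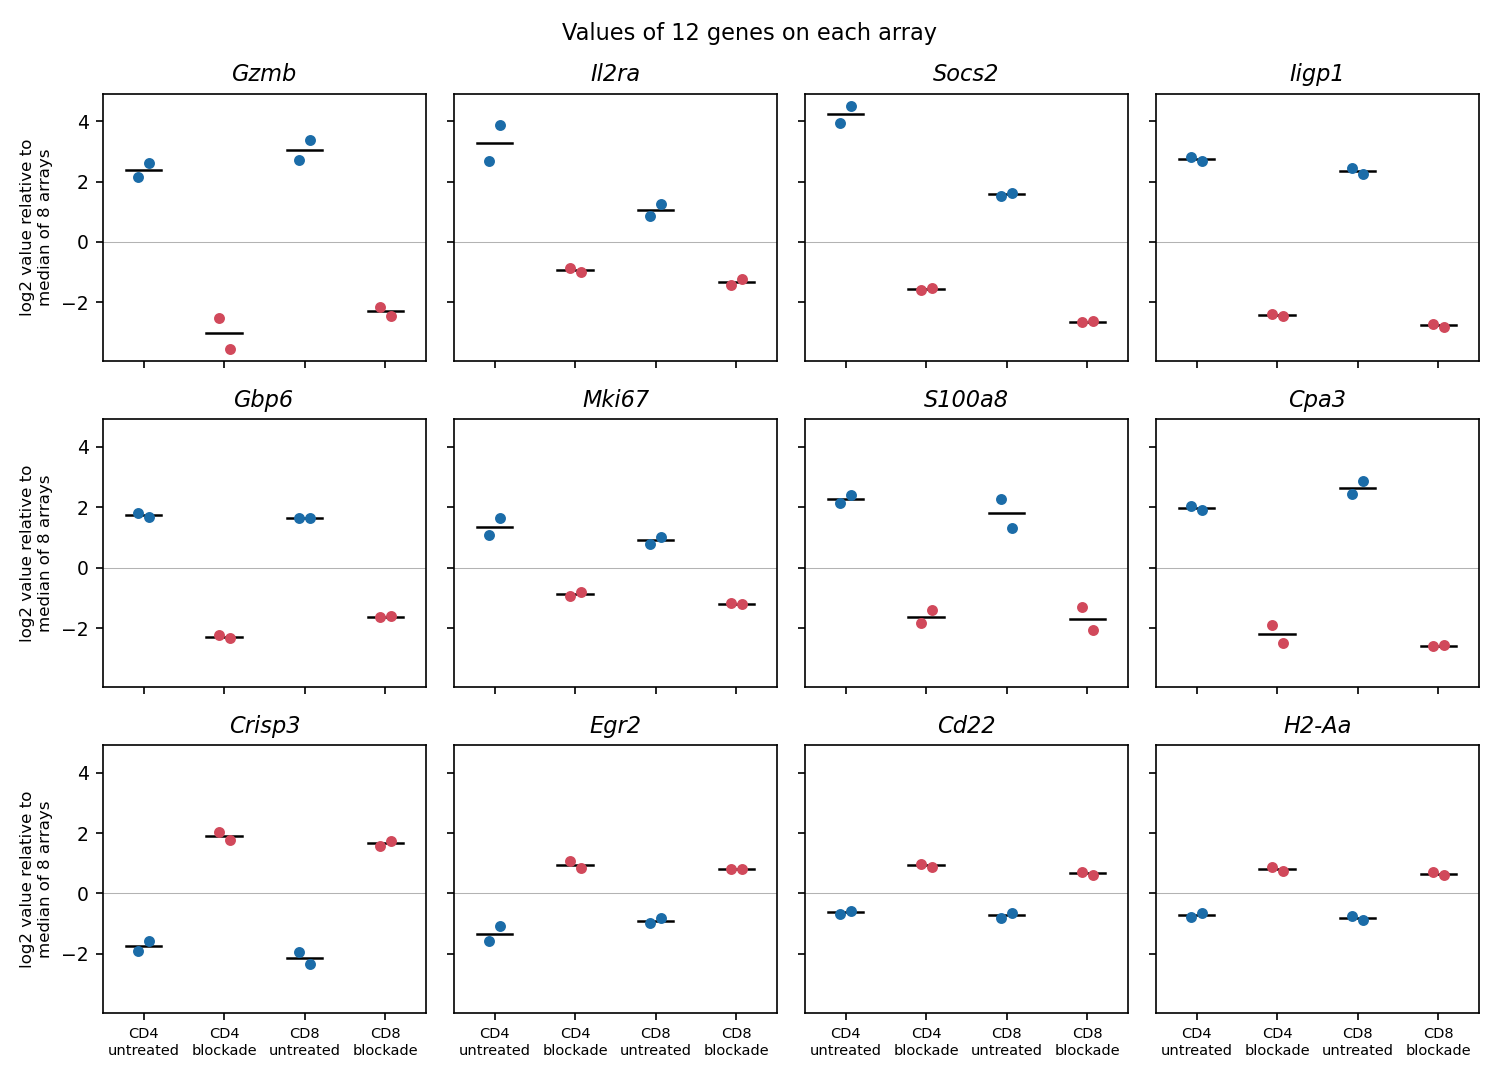
Values of 12 genes on each of the 8 arrays, as log2 differences from the gene's median over the arrays (vertical axis), for the 4 groups (horizontal axis). Each point is 1 array (blue untreated, red blockade) and each bar the mean of 2 arrays. In all 12 genes both blockade arrays lie apart from both untreated arrays of the same subset, as in all 289 named genes. These genes came from a list selected on these same arrays, so this is not independent evidence.

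The second comparison asked the same of CD8 cells. Among named genes the largest falls were those of Gzmb (-5.34 ± 0.34, adjusted p = 1.1e-04), Cpa3 (-5.23 ± 0.20, adjusted p = 8.2e-06), Iigp1 (-5.11 ± 0.11) and Penk (-4.24 ± 0.22). Socs2 changed by -4.21 ± 0.17, Tnfrsf9 by -2.93 ± 0.16 and Il2ra by -2.40 ± 0.32. Among the 10 largest falls of named genes were also the basophil and mast cell genes Mcpt8 (-3.83 ± 0.35) and Fcer1a (-3.67 ± 0.14) and the neutrophil granule genes S100a9 (-3.65 ± 0.46), Ngp (-3.55 ± 0.48) and S100a8 (-3.49 ± 0.34). Crisp3 rose by 3.80 ± 0.18, Apoe by 2.69 ± 0.13, Cr2 by 2.19 ± 0.14, Srpk3 (a protein kinase) by 2.16 ± 0.12 and Fcer2a by 2.06 ± 0.17. Il4i1, S1pr3, Bcar3, Fcmr and Pik3ap1 rose by 1.87 to 2.06. Among probe sets with no name here, 1458589_at and 1417185_at fell most (-4.50 ± 0.14 and -3.62 ± 0.15), and 1456147_at and 1456440_s_at rose most (1.62 ± 0.11 and 1.59 ± 0.14).

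Of 22 named mitosis and cell cycle genes, 19 fell in CD8 cells and 3 did not pass (22 adjusted over the list alone; camera adjusted p = 0.032; adjusted p = 0.69 with an estimated correlation). Top2a changed by -2.38 ± 0.19, Mki67 by -2.10 ± 0.17, Cdk1 by -1.91 ± 0.17 and Cdca3 by -1.42 ± 0.14. In the DNA replication list 3 of 5 fell (5 adjusted over the list alone; camera adjusted p = 0.43), namely Rrm2 (-2.39 ± 0.24), Uhrf1 (-1.95 ± 0.28) and Cdc6 (-1.81 ± 0.34). All 17 type I interferon genes fell (17 adjusted over the list alone; camera adjusted p = 0.0078; adjusted p = 0.33 with an estimated correlation). Ifit1 changed by -3.45 ± 0.12 and Ifit3 by -2.99 ± 0.10. Of 17 interferon-gamma genes, 15 fell, Ciita rose by 1.21 ± 0.12 and Cxcl10 lay at -0.65 ± 0.19 without passing (17 adjusted over the list alone; camera adjusted p = 0.011; adjusted p = 0.68 with an estimated correlation). Irgm2 changed by -3.34 ± 0.10, Gbp6 by -3.28 ± 0.10, Igtp by -2.70 ± 0.09 and Cd274 by -2.63 ± 0.11.

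Of 5 effector cytokines and chemokines, Penk, Ccl3 (-2.68 ± 0.16) and Csf2 (-1.54 ± 0.13) fell in CD8 cells and 2 did not pass (5 adjusted over the list alone; camera adjusted p = 0.29). All 4 activation receptors fell, with Tfrc at -1.37 ± 0.22 and Cd69 at -1.17 ± 0.16 (4 adjusted over the list alone; camera adjusted p = 0.29). Among anergy-associated genes Egr2 rose by 1.71 ± 0.17, whereas Nr4a3 and Nr4a2 fell (-1.57 ± 0.20 and -1.33 ± 0.25; 3 adjusted over the list alone; camera adjusted p = 0.79). Among naive and memory genes Il7r rose by 1.01 ± 0.09, and Bcl2 and Treml2 fell (-1.36 ± 0.10 and -1.21 ± 0.11; 3 adjusted over the list alone; camera adjusted p = 0.94). Of the integrated stress response genes, Asns changed by -2.76 ± 0.22, Psat1 by -1.82 ± 0.17 and Wars fell by 1.00 ± 0.10 (3 adjusted over the list alone; camera adjusted p = 0.29).

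In the sorted CD8 samples too, all 13 named B cell markers rose (13 adjusted over the list alone; camera adjusted p = 6.3e-08; adjusted p = 0.33 with an estimated correlation). Fcmr rose by 1.91 ± 0.12, Blnk (a B cell linker protein) by 1.71 ± 0.13 and Cd22 by 1.40 ± 0.10. Of 8 MHC class II presentation genes, 7 rose, H2-Ab1 by 1.64 ± 0.11, and Cd86 fell (-1.11 ± 0.20; 8 adjusted over the list alone; camera adjusted p = 4.1e-04; adjusted p = 0.36 with an estimated correlation). Of 9 neutrophil markers, 6 fell and 3 did not pass (9 adjusted over the list alone; camera adjusted p = 0.15, or 0.044 without CD8 untreated replicate 2). Ctsg changed by -2.98 ± 0.12, Mpo by -2.87 ± 0.13 and Prtn3 by -2.14 ± 0.19. The 4 hemoglobin probe sets rose by 1.29 to 1.92. The 5' minus 3' difference of Gapdh was -0.114 and -0.060 on the blockade arrays and 0.046 and 0.014 on the untreated arrays (beta-actin -0.040 and 0.051, and 0.009 and 0.023).

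In CD8 cells 1016 probe sets passed, 422 higher and 594 lower under blockade (148 and 289 with a change of at least 2-fold), of which 655 were outside the authors' list. A fit of only the 4 CD8 arrays called 577, without the calls of S100a9, Cd69, Cdc6, Nr4a2 and Tfrc, and leaving out 1 array gave 507 (without CD8 blockade replicate 1, the array with high spike-ins), 650 (without CD8 blockade replicate 2), 529 (without CD8 untreated replicate 1) or 502 (without CD8 untreated replicate 2). At adjusted p of at most 0.20 with the direction kept, the call of Cd86 was lost without any 1 of these arrays, those of Cdc6, Nr4a2, Tfrc and Uhrf1 without either blockade array or untreated replicate 2, that of Il2ra without blockade replicate 1 or untreated replicate 2, that of Nr4a3 without blockade replicate 1 and that of Cd69 without untreated replicate 2, when Ccl9 (-2.32) and Cxcl10 (-0.96) passed. Cdc6 and Nr4a2 were also lost without either CD4 blockade array (0.079 and 0.068), and Cdc6 with array quality weights (0.056), while Tk1 (-1.15) passed with quantile normalization (0.045). Without both arrays with unusual spike-ins the calls of Wars (0.051), Nr4a2, Tfrc, Cdc6 and Cd86 (0.12 to 0.20) were lost.

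**Figure D2:**
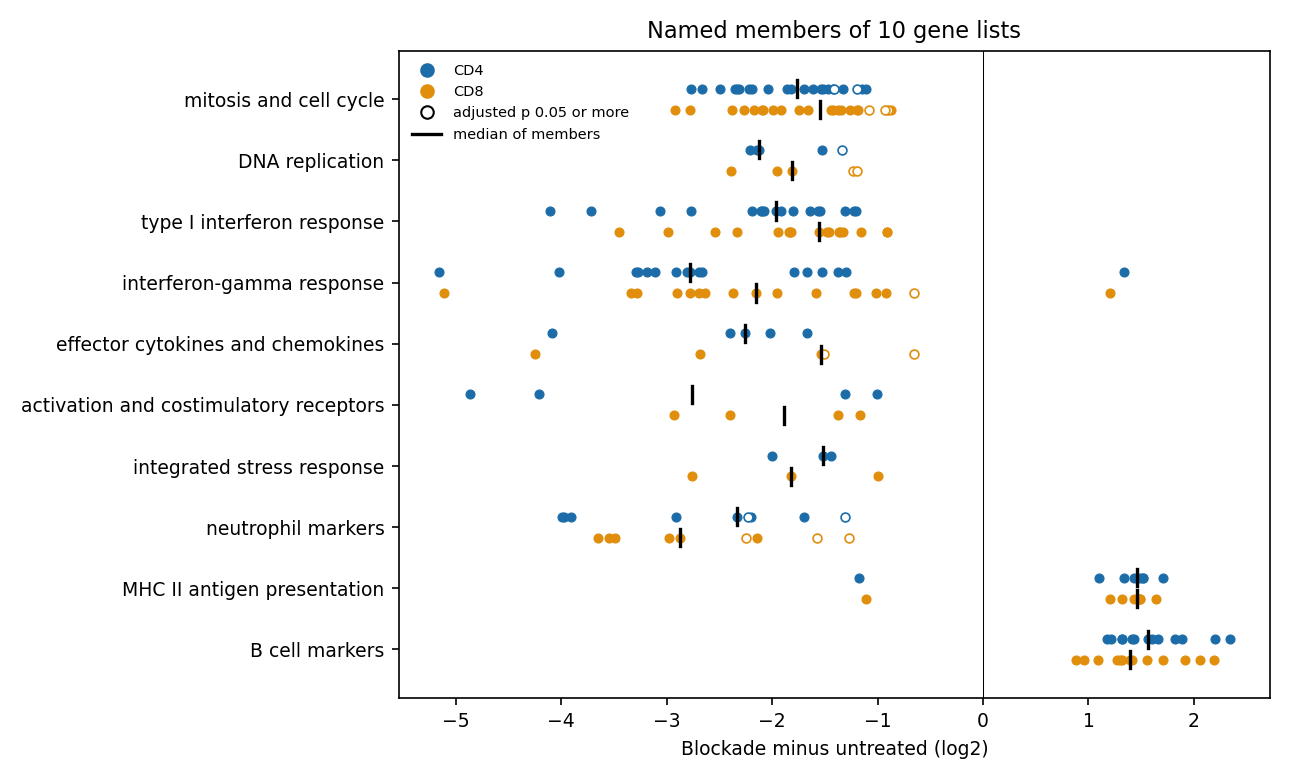
Change under blockade (blockade minus untreated, log2, horizontal axis) of the named members of 10 gene lists in CD4 (blue) and CD8 (orange) cells. Each point is 1 gene, open where the adjusted p was 0.05 or more, and vertical bars are list medians; all 13 B cell markers lie above 0 and all 22 cell cycle genes below 0 in both subsets.

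The calls of the CD4 and CD8 comparisons overlapped. Of the probe sets higher under blockade, 290 were called in both subsets, where independent lists would share 6.33. Of those lower, 484 were called in both, where independent lists would share 12.9 (one-sided Fisher's exact test, log10 of p -448.6 and -746.6). Another 3 probe sets were called in opposite directions. Both sets of calls came from one fit with variances pooled over all 8 arrays, so they lack the independence that the test assumes. In 2 separate fits of the 4 arrays of each subset, chosen after seeing the data, 156 probe sets were higher in both (555 in CD4 and 205 in CD8, where independent lists would share 2.53) and 314 lower in both (836 and 372, where independent lists would share 6.91), with 1 called in opposite directions. Whether CD4 and CD8 cells were sorted from the same cultures is not known here. If they were, anything particular to a culture would move both subsets alike, and these fits would not be independent either. Across all probe sets, which are not independent replicates, the changes in CD4 and CD8 cells correlated with a Pearson r of 0.72 and a Spearman rho of 0.41. Among the 1489 probe sets called in either subset and outside the authors' list, 93.8% changed in the same direction. The number shared in one direction, 774, was 501 without CD4 blockade replicate 1, 497 without CD4 blockade replicate 2, 441 without CD8 blockade replicate 1, 490 without CD8 blockade replicate 2, 461 without CD8 untreated replicate 1 and 435 without CD8 untreated replicate 2.

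**Figure D3:**
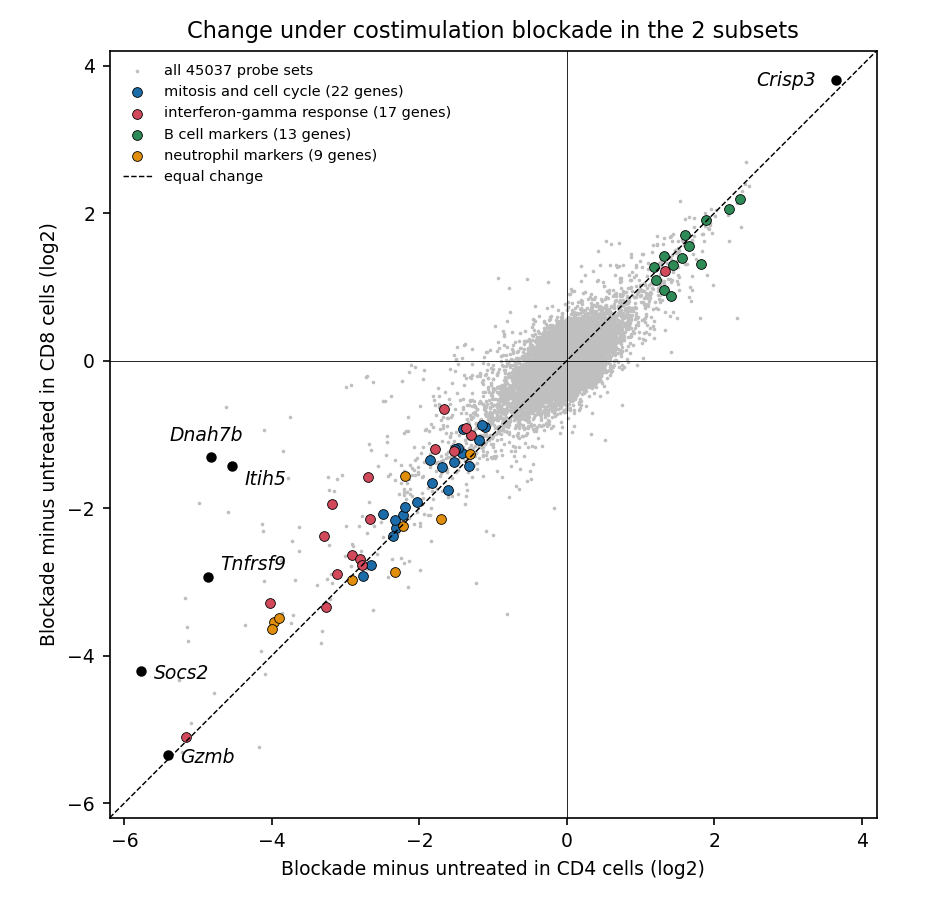
Change under blockade (blockade minus untreated, log2) in CD4 cells (horizontal axis) and CD8 cells (vertical axis) for all 45037 probe sets (grey), with named members of 4 gene lists in colour and 6 genes labelled in black. The dashed line marks equal change; Dnah7b, Itih5 and Tnfrsf9 lie above it, with a smaller fall in CD8 than in CD4 cells.

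Few named genes passed the test of a difference between the subsets in their response. All of them came from the authors' list, whose probe sets changed at least 2-fold averaged over both subsets, so genes that respond differently may be missing from it. Of the 28 probe sets called for the difference, 22 were outside that list. The difference (CD8 effect minus CD4 effect) was 3.51 ± 0.29 for Dnah7b (adjusted p = 0.0076), 3.11 ± 0.21 for Itih5 (adjusted p = 0.0031), 1.94 ± 0.23 for Tnfrsf9 (adjusted p = 0.043) and 1.23 ± 0.15 for Gbp3 (a guanylate-binding protein, adjusted p = 0.041). Dnah7b changed by -4.82 in CD4 and by -1.31 in CD8 cells, a CD8 call lost without any 1 CD8 array, and Itih5 by -4.54 and -1.43. Il2ra changed by -4.21 and -2.40, but that difference did not pass (1.81 ± 0.45, adjusted p = 0.59), and Gzmb had a difference of 0.06 ± 0.47. Dnah7b, Itih5 and Il2ra were already lower in CD8 than in CD4 cells without treatment, as given below. Their smaller fall in CD8 cells may therefore reflect a lower starting level. Centred values hold no signal level, so this could not be examined. The members of the interferon-gamma list had a median difference of 0.30 and lay above the other named genes by camera (adjusted p = 0.011; adjusted p = 0.78 with an estimated correlation). Of these 17, 1 passed the gene test (8 adjusted over the list alone). B cell markers had a median difference of -0.14 and lay below (camera adjusted p = 0.022; adjusted p = 0.78 with an estimated correlation), with none of 13 past the gene test (0 adjusted over the list alone). Among probe sets called in both subsets, the CD4 effect was larger in size for 65.6%, with a median CD8 over CD4 effect of 0.91. Smaller effects in CD8 cells in general would place a falling list above and a rising list below. These list results therefore need not be particular to the lists.

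Over all probe sets, 28 passed for the difference, 26 with a more positive and 2 with a more negative effect in CD8 cells (19 with quantile normalization, 15 and 4). Of the 28, 20 were lower under blockade in both subsets, so a more positive effect was often a smaller fall. Of all probe sets, 2253 had an unadjusted p under 0.05, where 2252 are expected with no difference at all. Without both arrays with unusual spike-ins none passed by limma and 2130 had an unadjusted p under 0.05; Dnah7b (3.18) and Itih5 (2.91) then had adjusted p-values of 0.14, Gbp3 of 0.48 and Tnfrsf9 of 0.53. The count was 5 without CD4 blockade replicate 1 or 2, 11 without CD4 untreated replicate 2 or CD8 blockade replicate 1, 9 without CD8 blockade replicate 2, 18 without CD8 untreated replicate 1 and 14 without CD8 untreated replicate 2. The calls of Tnfrsf9 and Gbp3 ended with quantile normalization (differences of 0.82 and 0.73, adjusted p = 0.48 and 0.35). That of Tnfrsf9 was also lost with array quality weights (0.053) and without any 1 array other than CD4 untreated replicate 1 (adjusted p 0.11 to 0.23), that of Gbp3 without any 1 of the 8 (0.093 to 0.26) and that of Dnah7b without any 1 blockade array (0.062 to 0.082). Both list calls ended with quantile normalization, at adjusted p of 0.63 for interferon-gamma and 0.49 for B cells. The former was also lost without CD4 untreated replicate 1 (0.39), and the latter without CD4 untreated replicate 1 (0.051) or 2 (0.07) or CD8 untreated replicate 1 (0.16). Type I interferon genes, at 0.057, passed without CD4 blockade replicate 2 (0.044), CD4 untreated replicate 2 (0.019) or CD8 blockade replicate 1 (0.040), or without the last 2 together (0.019). Neutrophil markers, at 0.37, passed without CD8 blockade replicate 1 (0.036), CD8 untreated replicate 2 (0.037) or both arrays with unusual spike-ins (0.038), when B cell markers did not (0.067). Among probe sets with no name here, 1424800_at and 1441946_at had the largest positive differences (3.99 ± 0.40 and 2.98 ± 0.30) and 1450495_a_at and 1460118_at the largest negative ones (-1.82 ± 0.20 and -1.74 ± 0.18).

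Averaged over both subsets, all 289 named genes passed, 81 higher and 208 lower under blockade, from Gzmb at -5.38 to Crisp3 at 3.72. Their names came only from the authors' list, whose probe sets all differed at least 2-fold in this same average. That they all passed is therefore no separate result. Of all probe sets 3267 passed, 1567 higher and 1700 lower; with a change of at least 2-fold these were 558, 161 higher and 397 lower. The count fell to 2134 without CD4 blockade replicate 1, 1934 without CD4 blockade replicate 2, 1794 without CD4 untreated replicate 2 and 2007 without CD8 untreated replicate 2.

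The subsets were also compared with each other at the same treatment (CD8 minus CD4). In untreated cultures the difference was -3.91 ± 0.21 for Dnah7b, -3.62 ± 0.15 for Itih5, -2.64 ± 0.17 for Socs2, -2.58 ± 0.27 for Ifitm3 and -2.21 ± 0.32 for Il2ra. Tspan9 (a tetraspanin) was higher in CD8 cells by 1.01 ± 0.15, Ccl3 by 0.96 ± 0.16, Cma1 (mast cell chymase) by 0.87 ± 0.16, Cd72 by 0.73 ± 0.11 and Ifit3 by 0.48 ± 0.10. Under blockade, Ifit3 was higher in CD8 cells by 1.59 ± 0.10, Socs1 (an inhibitor of cytokine signalling) by 1.27 ± 0.14, Ifit1bl1 by 0.86 ± 0.11, Tmem140 by 0.82 ± 0.11 and Gbp2 by 0.80 ± 0.09. Socs2, Serpina3g and Treml2 lay at -1.08 ± 0.17, -0.83 ± 0.13 and -0.65 ± 0.11.

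Of all probe sets, 1130 differed between CD8 and CD4 cells without treatment, 485 higher and 645 lower in CD8, and 988 under blockade, 486 higher and 502 lower. Of these, 41 and 18 were in the authors' list. Among probe sets with no name here, the largest differences in untreated cells were those of 1451673_at and 1444078_at (7.01 ± 0.16 and 6.68 ± 0.16) and of 1417928_at and 1456440_s_at (-4.69 ± 0.13 and -4.50 ± 0.14). The untreated count was 742 without CD4 untreated replicate 1, 560 without CD4 untreated replicate 2, 673 without CD8 untreated replicate 1 and 688 without CD8 untreated replicate 2. The blockade count was 533 without CD4 blockade replicate 1, 506 without CD4 blockade replicate 2, 566 without CD8 blockade replicate 1 and 632 in a fit of the 4 blockade arrays. In untreated cells the calls of Cd72 and Cma1 were lost without any 1 untreated array (adjusted p 0.052 to 0.19) and that of Ifit3 without any 1 of the 8 arrays (0.054 to 0.26) and with each array centred on its median (0.051). The call of Ccl3 was lost without either untreated replicate 2 (0.14 and 0.12), that of Tspan9 without CD4 untreated replicate 2 (0.083) or CD8 untreated replicate 1 (0.060), and that of Il2ra without CD8 untreated replicate 1 (0.055). Under blockade the call of Socs2 was lost without any 1 blockade array (0.063 to 0.11), that of Serpina3g without either CD4 blockade array or CD8 blockade replicate 2 (0.052 to 0.13), that of Treml2 without either CD4 blockade array or CD8 blockade replicate 1 (0.10 to 0.12) and that of Tmem140 without CD4 blockade replicate 1 (0.052). Without both arrays with unusual spike-ins the calls of Ifit1bl1 (0.086), Tmem140 (0.074), Gbp2 (0.065) and Treml2 (0.19) under blockade were lost, as were those of Tspan9, Ccl3, Cma1, Cd72 and Ifit3 in untreated cells (0.058 to 0.31).

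The authors' deposited list held 409 probe sets, 129 higher and 280 lower under blockade. Every listed probe set changed in the same direction in CD4 and CD8 cells in the fit made here. In that fit 394 passed in CD4 cells, 361 in CD8 cells and 355 in both. The list was selected on these same arrays, and its probe sets all differed at least 2-fold in the average over both subsets. Neither the shared direction nor these counts are therefore independent evidence.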

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

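The tests of the authors' normalization and of the probe sets that passed without 1 array were chosen only after the result was seen. Groups of 2 arrays are too small for a test of single arrays that stand apart.

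For 28 probe sets the effect of blockade differed between CD8 and CD4 cells by the test of the difference itself. Among named genes this held for Dnah7b (3.51), Itih5 (3.11), Tnfrsf9 (1.94) and Gbp3 (1.23, log2, CD8 effect minus CD4 effect). It also held by camera for the interferon-gamma list (median difference 0.30) and for B cell markers (-0.14), though for neither with an estimated correlation. Smaller effects in CD8 cells in general would give these directions too.

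Of the 28 probe sets, 20 were lower under blockade in both subsets. The first pattern is that 26 of the 28 differences (CD8 effect minus CD4 effect) were positive, which need not be a rise in CD8 cells. If the array of CD8 blockade replicate 1 with its high spike-in signal were the source, they should not pass without it; 10 of the 28 passed in a fit that left it out, which argues against it for those 10, although none passed by limma when CD4 untreated replicate 2 was left out as well (2130 had an unadjusted p under 0.05). For the other 18 it stays open: the median size of the 28 without that array, 1.92 against 2.00 with all, decides nothing, since they were selected with that array in the fit. The authors' normalization stays open: 15 of the 28 were called with quantile normalization added, with a median size of 1.67, and 28 with each array centred on its median. A biological difference between the subsets was not tested further and stays open. For Dnah7b and Itih5, a different response cannot be told from their lower starting level in untreated CD8 cells.

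Control probe sets, which no comparison used, gave higher values on some blockade arrays than on any untreated array. Hybridization spike-ins had medians of 0.10 and 0.13 on the arrays of CD4 blockade replicates 1 and 2 and 0.92 on CD8 blockade replicate 1, against at most 0.0074 on untreated arrays. Poly-A spike-ins had a median of 0.84 on CD8 blockade replicate 1, against at most 0.25. Ribosomal 18S probe sets had medians of 0.73 on CD4 blockade replicate 2 and 1.00 on CD8 blockade replicate 2, against at most 0.30.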

How the results depend on the processing

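Leaving out both arrays with the highest and lowest spike-in medians (CD8 blockade replicate 1 and CD4 untreated replicate 2) was chosen after seeing the data, as were the overlap of separate fits and Fisher's exact test of list directions. Of 196 values of named genes, 144 kept their direction and side of the threshold under all of the 14 alternatives run for them. None of the 196 changed direction. Fits of only the 4 arrays compared were not run for the difference between subsets. In all 289 named genes both blockade arrays lay apart from both untreated arrays of the same subset. Leaving out arrays could therefore not reverse a blockade effect in CD4 or CD8 cells, and the kept direction there shows nothing further. Centred values hold no signal over background, so what dim signal limits could not be examined. For the counts, a fold minimum of 2 gave 652 in CD4, 437 in CD8, 558 averaged, and 469 and 408 between the subsets untreated and under blockade. An adjusted p under 0.01 gave 815, 474, 1504, 628 and 532, with 9 for the difference and 393 shared. The methods' t-test gave, at an unadjusted p of 0.05, 4978 in CD4 (2653 higher, 2325 lower), 4780 in CD8 (2469 and 2311), 4317 and 3776 between the subsets, and after Benjamini-Hochberg 3, 1, 0 and 7; it has fewer degrees of freedom. A fit of only the 4 arrays compared gave 577 in CD8 and 632 between the subsets under blockade, and 2 such fits shared 470. Beside the CD8 calls named above, such fits lost Iglv1 in CD8 (limma adjusted p 0.057) and Tk1 in CD4 cells (0.052). Between untreated subsets they lost Il2ra (0.052), Ccl3 (0.060) and Ifit3 (0.084), and under blockade Serpina3g (0.063) and Treml2 (0.054). Without both arrays with unusual spike-ins the counts were 634 in CD4, 372 in CD8, 0 for the difference by limma (2130 at an unadjusted p under 0.05), 1269 averaged, 466 and 391 between the subsets and 289 shared, from fewer arrays. Without 1 array they ranged from 768 to 1516 in CD4, 502 to 890 in CD8, 5 to 26 for the difference, 1794 to 2553 averaged, 560 to 1075 and 506 to 882 between the subsets, and 435 to 625 shared; 277 to 352 listed probe sets passed in both subsets, and 10 to 14 list tests. Of 36 list tests 12 passed with the preset correlation, 0 with an estimated one and 24 with fry, which compares no list with other genes; Fisher's exact test of direction passed 8. The cause was not tested for the other changes. Same-numbered arrays did not deviate together (correlations of the replicate differences across probe sets -0.03 to 0.08), so the values gave no sign that the numbers pair samples. Whether the samples were paired in the experiment cannot be told from this. With the replicate block the counts were 1504 in CD4, 940 in CD8, 26 for the difference, 2833 averaged, 1024 and 911 between the subsets, 732 shared, 360 listed and 12 list tests; among named genes 5 calls were lost, those of Tnfrsf9 and Gbp3 for the difference (adjusted p 0.072 and 0.075), Fabp4 in CD4 (0.058), Cd86 in CD8 (0.053) and Ifit3 between untreated subsets (0.064), and 2 gained in CD8, Tk1 (0.048) and Tpi1 (0.040). The filter on dim probe sets, the intensity trend and log offsets were not run, since the values hold no signal level.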

Other observations

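The test of the marker list gap and the comparison with lists that mark no other cell type were chosen after the result was seen, and the mast cell and basophil list was written after the gene names were seen. Gene lists with 1 or 2 named members were not tested as lists. Under blockade the glycolysis gene Hk2 (hexokinase) fell by 1.64 ± 0.17 in CD4 and by 1.26 ± 0.17 in CD8 cells, and Tpi1 lay at -1.23 ± 0.21 and, without passing, at -0.93 ± 0.21 (in CD8 cells it passed with quantile normalization, adjusted p 0.0097, or without either CD4 untreated array, 0.015); the Gapdh control probe sets had medians of -0.12 to -0.34 on blockade and 0.12 to 0.50 on untreated arrays. Idi1 (isoprenoid synthesis) fell by 1.34 ± 0.20 and 1.62 ± 0.20, Cdkn1a (the cell cycle inhibitor p21, a p53 target) by 2.30 ± 0.19 and 1.73 ± 0.19 and Tap1 (peptide transport) by 1.37 ± 0.10 and 0.92 ± 0.10. Xbp1 fell by 1.23 ± 0.11 and 0.85 ± 0.11, Serpinb6b by 1.71 ± 0.23 and 1.53 ± 0.23, Bst2 by 2.10 ± 0.11 and 1.84 ± 0.11 and Fscn1 by 3.87 ± 0.47 and 2.70 ± 0.47, the last lost in CD8 cells without any 1 CD8 array or CD4 blockade array (adjusted p 0.059 to 0.17). Egr1 rose by 1.66 ± 0.14 and 1.58 ± 0.14, Ccr6 (a chemokine receptor) by 1.16 ± 0.12 and 1.56 ± 0.12, Cybb by 1.30 ± 0.16 and 1.22 ± 0.16 and Iglv1 by 1.32 ± 0.17 and 1.21 ± 0.17. Blk rose by 1.66 ± 0.12 and 1.56 ± 0.12, and Trgv4, a T cell receptor gamma segment, lay at -2.15 ± 0.26 and, without passing, at -0.76 ± 0.26. Without 1 array of the same subset, the calls of Serpinb6b, Tpi1 and Idi1 in CD4 cells and of Hk2, Serpinb6b, Cybb and Iglv1 in CD8 cells were also lost for some arrays (adjusted p 0.05 to 0.11), with the direction kept. Without both CD8 blockade replicate 1 and CD4 untreated replicate 2, the calls of Cybb, Iglv1, Idi1 and Tpi1 in CD4 cells (0.053 to 0.064) and of Cybb, Iglv1, Tap1 and Xbp1 in CD8 cells (0.058 to 0.14) were lost. The lists for ribosome biogenesis, oxidative phosphorylation, T cell receptor signalling, apoptosis promotion, NK cells, platelets and the CD4 and CD8 subsets had no named member.

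The second pattern is the rise of B cell markers under blockade in both sorted subsets. A general loss of T cells from the blockade samples would, with no other change, raise the markers of every other cell type alike. The neutrophil median lay below the B cell median by -3.89 in CD4 and -4.27 in CD8 cells, with SDs of members of at most 1.02 and 0.877. Such a loss alone would not lower the named neutrophil markers, which fell. This cannot decide whether such a loss raised the B cell markers, since the neutrophil markers may have fallen for a separate reason. Hemoglobin probe sets and the 2 named macrophage markers, Apoe and Cybb, rose too. The size of the gap is partly set by selection, since every named gene came from a list of probe sets changed at least 2-fold. More B cells among the sorted cells stays open. The 13 genes moved together between arrays of one group. Their mean pairwise correlation of the replicate differences was 0.283, against a 95th percentile of 0.249 in 1000 random sets of named genes. This correlation, here and below, was taken about 0 and rests on only 4 differences per gene, 1 from each group. But 5 of 9 lists that mark no other cell type also moved together (0.268 for interferon-gamma, 0.707 for mitosis, 0.634 to 0.944 for 3 others), while 4 did not (-0.054 to 0.164). The measure therefore does not tell a share of B cells from genes regulated together within the T cells. The gate on CFSE and CD4 or CD8 should remove B cells, Blk is also on the list of gamma-delta T cells, all 13 were picked from these arrays by the authors' list, the levels of these genes are unknown, and an effect of blockade on the T cells themselves stays open, untested.

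The third pattern is the fall of granulocyte genes in both subsets. The 7 named genes of a mast cell and basophil list of 14 had a median change of -2.63 in CD4, where 7 fell, and -3.38 in CD8, where 6 fell; Tph1, Cyp11a1 and Ms4a2, named after their values were seen, lay at -2.57, -1.22 and -1.13 in CD4 cells. The 9 neutrophil genes moved together between arrays of one group (mean pairwise correlation 0.413, against a 95th percentile of 0.321), but so did 5 of the same 9 lists, so fewer neutrophils or their precursors among the cells sorted under blockade, which the gate should remove too, stay open. The mast cell and basophil genes did not (0.0596, against 0.364), which leaves that source open, since its share need not differ between replicates. A change within the T cells stays open, untested.

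Splitting the arrays did not exclude chance for the averaged effect of blockade. The labels do not say that the 8 arrays are separate samples. If the 2 arrays of a group share a culture, the splits that keep them together are too few to decide. In a model with the subset as a term, 34 splits of the 8 arrays into 4 and 4 were fitted. The real split gave 3430 probe sets, and the highest of the others gave 0. Many of these splits divide the arrays of a subset unevenly, unlike the real one, and are not equivalent to it. Those that divide each subset evenly are too few for a share under 0.05, even if all arrays are separate samples. The split equal to the subsets could not be fitted in that model.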
